A study of Mus musculus with 4 samples.

How the data were processed

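The series measured RNA in bone marrow cells of 12-week-old male db/db and db/+ mice, cultured for 7 to 8 days in 10 ng/ml of M-CSF or 20 ng/ml of GM-CSF, with 4 libraries in 4 groups of 1 library each, as the labels give them. Total RNA was depleted of ribosomal RNA and sequenced in read pairs on an Illumina HiSeq instrument, per the labels' protocols. Whether each library came from 1 animal or from pooled animals, and whether the libraries keep the strand of the RNA, is not given in the sources used here, so overlapping and antisense genes cannot be separated. The read names in the labels place all 4 libraries in 1 sequencing lane, so no lane batch could be compared.

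The deposited files hold a normalised signal per gene, that is read counts divided by a size factor for each library and rounded to 1 decimal, in 22700 rows per library. Per the submitters' processing notes TopHat 1.2.0 and edgeR were used, and the mouse builds mm8 and mm9 are named without a role. The size factors are edgeR's TMM factors by the name that the authors gave the deposited files. The counting tool, the annotation and any filter are not given in the sources used here. The reference used here for gene names is of another mouse build, so no coordinates are printed. For E330013P06 that reference gives the current symbol Carmn and the class of long noncoding RNA. Of the symbols, 38 stood in more than 1 row (78 rows in all) and 25 had the form of a date; these were kept in the tests and are not named in the text. No per-sample columns were left unused (0 such columns).

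Design choices assumed either counts or a normalised unit, and the files hold the latter, so limma on log values was the main test and the count test was run as an alternative. Whole read counts were recovered from the deposited values by dividing by the step of 1 read, which was 0.951, 0.871, 1.12 and 1.08 in the db/+ and db/db M-CSF and the db/+ and db/db GM-CSF libraries. With a tolerance of 0.1, all low values came out whole (100% in each library), as did 99.9%, 99.5%, 99.5% and 99.8% of all values. Even multiples were commoner than odd ones at low counts, from which mates of a pair appear to have been counted separately, so intervals and sampling draws used read pairs. Depth was 25603390, 27590739, 27216091 and 28622694 reads in the same order, or 12801695, 13795369, 13608045 and 14311347 pairs. The floor of 3 read pairs was 5.71, 5.23, 6.73 and 6.45 normalised reads. The 10 most abundant genes took 9.59%, 8.92%, 15.7% and 15.7% of reads, and 2518, 3882, 6738 and 6648 genes were at 0.

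Genes whose value reached a level minimum of 20 in at least 1 of the 4 libraries were kept, 13642 in all. Log2 folds were taken on log2(value + 5). With 1 library per group, the 4 pairwise comparisons were described by the number of genes at least 2-fold apart, beside the mean of 100 draws in which read pairs were split between the compared libraries at random. Ratios were given exact conditional binomial 95% intervals, and shares of reads Wilson intervals. In the log2 folds, and so in the counts and rankings, a library at 0 stands at the pseudocount. A fold written as "at least" against a library at 0 was computed against 3 read pairs in that library. The main effects of genotype and of culture type were tested with limma (lmFit and eBayes with a variance trend) on an additive model of both factors. That model has 1 residual degree of freedom, moderated by a prior with 12.87, and no interaction could be tested. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, two-sided.

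Gene lists, 32 in all, were fixed from general knowledge of macrophages, metabolism and the other cell types of marrow: label checks, growth factor receptors, M-CSF macrophage markers, GM-CSF culture markers, inflammatory genes, alternative activation, interferon-stimulated genes, MHC class II, lipid uptake, cholesterol synthesis, fatty acid synthesis, glycolysis, oxidative phosphorylation, oxidative stress, endoplasmic reticulum stress, cell cycle, scavenger and complement genes, matrix remodelling, stromal, neutrophil, erythroid, B cell, T and NK cell, mast cell, eosinophil, osteoclast and dendritic cell markers, histones, ribosomal proteins, long noncoding RNAs, immediate early genes, and growth factors. In each pairwise comparison a list's median log2 fold was placed among those of 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. The MHC class II list also holds Cd80, Cd86, Cd40 and Cd83, which are not class II genes, and its values below are those of the whole list. A list was said to stand apart below percentile 2.5 or above 97.5. In the main effects, lists were tested with camera at a preset inter-gene correlation of 0.01 and again with a correlation estimated from the residuals. Where genes stood at 0, list medians were also computed with those genes at 3 read pairs.

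The genes named in the text were set by rule: the 10 highest and 10 lowest folds of each genotype comparison, the 10 highest and 10 lowest by the smaller fold among genes of the same direction across cultures or across genotypes, the 5 smallest adjusted p-values of each main effect, the 5 largest differences in each direction between the genotype folds of both cultures, members of the lists, and E330013P06, which the study is known to have followed up. Results for some genes that this rule names are not reported here. Rn45s, the olfactory receptor genes and the second stromal list of the closing section were chosen after their values were seen. The comparisons, the tests, the lists, the naming rule and the alternatives, except where another time is stated, were fixed before the data were examined.

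Alternatives were pseudocounts of 1 and 20, no filter and a level minimum of 200, median-of-ratios scaling, folds centred on the median of kept genes, thresholds of 1.5-fold and 3-fold, limma without a variance trend or without the other factor, edgeR's quasi-likelihood test on the recovered reads, and an estimated correlation. A level minimum reached in 1 of the 2 libraries compared, and libraries at 0 set to 3 read pairs, were added after seeing the data. Other splits of the samples were not counted, since no group has 3 libraries. The limma step was tested on simulated data, in which counts for all 13642 genes were drawn with a biological coefficient of variation of 8.88%. For genotype it recovered 86% of 100 genes changed 2-fold and 100% of 100 changed 4-fold, with 0 false calls among 13442 unchanged genes. For culture type it recovered 97% and 100%, with 8 false calls. The changed genes had a mean of at least 100 reads, and each change was the same at both levels of the other factor. The coefficient was 1 for all libraries, whereas it was 15% between the M-CSF and 1.84% between the GM-CSF libraries. These rates therefore do not describe genes with few reads or genes whose genotype fold is confined to 1 culture type. Computations used R 4.3.3, limma 3.58.1, edgeR 4.0.16, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.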

Results

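Gene expression was measured by paired-end sequencing of ribosome-depleted total RNA from bone marrow cells of 12-week-old male mice. The donors were obese, diabetic db/db mice, which carry a splice mutation in the leptin receptor gene Lepr, or their lean db/+ littermates. The marrow was cultured for 7 to 8 days with 10 ng/ml of M-CSF, which drives macrophage differentiation, or with 20 ng/ml of GM-CSF, which yields macrophages and cells with dendritic features. The design crossed genotype with culture type and gave 4 groups of 1 library each, so no difference between a pair of libraries had a replicate check. The read counts recovered from the deposited values came to 25603390 in the db/+ and 27590739 in the db/db M-CSF library, and to 27216091 and 28622694 in the corresponding GM-CSF libraries. Levels are given as normalised read counts, and log2 folds were taken on log2(normalised count + 5), which understates the change of genes with few reads. Intervals are 95% exact intervals on read pairs. PCR reads are not independent molecules, so these intervals cover counting error only.

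Lepr was at 6.7 normalised reads in the db/+ and 21.8 in the db/db M-CSF library, from 7 and 25 reads, a ratio of 3.27 with an interval of 0.951 to 15.5. In GM-CSF it was at 49.4 in db/+ and 60.3 in db/db, a ratio of 1.22 (0.674 to 2.24). The db mutation alters splicing of the long receptor form, so the total over the gene does not check the genotype. The Y-linked Ddx3y was at 2155, 2820.5, 2566 and 2660.4 in the db/+ and db/db M-CSF and the db/+ and db/db GM-CSF libraries, and the X-inactivation RNA Xist was at 19, 2.6, 0 and 0 in the same order. Across the 6 measured genes of this label-check list the M-CSF median log2 fold of db/db over db/+ was 0.22, at percentile 99.1 of random lists, and the GM-CSF median was 0.02. The M-CSF db/+ library also had the broadest low-level signal, with reads on 526 of 1123 olfactory receptor genes (46.8%), against 331 in db/db M-CSF and 114 and 96 in db/+ and db/db GM-CSF.

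The first comparison asked how cells from diabetic mice differed from control cells after culture in M-CSF. The db/db library held more transcripts of fibroblast and stromal markers and of matrix remodelling genes, and fewer transcripts of interferon-stimulated and MHC class II genes. Sparc, a collagen-binding matrix protein, was at 13327 normalised reads in db/db against 4400.0 in db/+, a ratio of 3.03 (2.89 to 3.17). Timp3, an inhibitor of matrix metalloproteinases, was at 12275 against 3565, a ratio of 3.44 (3.27 to 3.63). Ifi44, the only 1 of 38 measured interferon-stimulated genes at least 2-fold lower, was at 525 against 1174, a ratio of 0.448 (0.389 to 0.515). In all, 689 genes were at least 2-fold higher and 106 at least 2-fold lower in db/db among the 13642 genes that reached the level minimum of 20, a total of 795. With no filter, 812 were higher and 554 lower. Random sampling of read pairs with no difference gave a mean total of 88.9. With the level minimum at 200 the total was 334 against 8.23 from sampling.

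Of the 21 measured fibroblast and stromal markers, 18 were at least 2-fold higher in db/db and 0 were at least 2-fold lower, and their median log2 fold of 1.38 lay above the medians of all 10000 matched random lists. The type I collagen chains Col1a1 and Col1a2 were at 5709 and 22962 in db/db against 2273 and 8292 in db/+. Postn, a matricellular protein of fibroblasts, was at 10631 against 3455. The smooth muscle actin gene Acta2 was at 15145 against 6125, and Cxcl12, a chemokine made by marrow stroma, was at 2829 against 923. The exceptions were Pdgfra at a log2 fold of 0.79, Igfbp4 at -0.12 and Thy1 at -0.80. In GM-CSF 8 of the 21 reached the minimum in a library: Col1a2 was at 13.5 in db/+ and 21.5 in db/db, and Fstl1, a secreted glycoprotein, at 19499.7 and 19329.9. Of all 689 genes that were higher in db/db M-CSF, 440 (63.9%) lay under the minimum in both GM-CSF libraries, against 9.09% of all genes kept. So did 45 (42.5%) of the 106 genes that were lower, so a share above 9.09% was not particular to the higher genes.

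The matrix remodelling list had 10 of 26 measured members at least 2-fold higher in db/db M-CSF, a median log2 fold of 0.32, and a percentile of 100 among random lists, next to the stromal median of 1.38 in the same libraries. Fn1, the gene of fibronectin, was at 40483 against 13859, and the collagen cross-linking enzyme Lox at 9088 against 2998. Spp1, which encodes osteopontin, was at 25754 against 11355. Growth factors and wound repair genes were higher in 8 and lower in 6 of 14 members, with a median of 0.25 at percentile 99.2, and 2 were at least 2-fold higher: Thbs1, which encodes thrombospondin, at 22987 against 10664 and Tgfb2 at 417 against 173. Csf1, the gene of M-CSF itself, was at 6065 against 2485, a ratio of 2.44 (2.29 to 2.60), while the growth factor receptor list that holds it had a median of -0.13 and a mean of 0.02.

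Among interferon-stimulated genes, 37 of 38 measured members were lower in db/db M-CSF, with a median log2 fold of -0.23 and quartiles of -0.37 and -0.14, below all 10000 random lists, and 1 member, Ifi44, at least 2-fold lower. Ifi27l2a was at 2423 against 4235, Iigp1, an interferon-inducible GTPase, at 464 against 816, and Oas3, a sensor of double-stranded RNA, at 3037 against 4572. Gbp2 was the exception at 0.54. The MHC class II list, which also holds Cd80, Cd86, Cd40 and Cd83, had 11 of 15 members lower, 0 of them at least 2-fold. Its median was -0.39, again below all random lists, and its mean -0.21. The invariant chain Cd74 was at 37748 against 49679.8, H2-Aa at 12333 against 16174, and Ciita, the transactivator of class II genes, at 1740.1 against 2629.9. Ribosomal protein genes were lower in 38 of 52 members (median -0.14, below all random lists), and scavenger, complement and Fc receptor genes in 21 of 27 (median -0.14, percentile 0.35). Smaller shifts were seen for histone genes (median -0.07, percentile 0.65) and alternative activation genes (median -0.10, percentile 1.97).

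Cell cycle genes were higher in db/db M-CSF in 25 of 33 members, with a median log2 fold of 0.18 at percentile 99.8, next to the stromal median of 1.38 in the same libraries. Ccnd1, which encodes cyclin D1, was at 2554 against 1479. Cholesterol synthesis genes were higher in 17 of 24 members, with a median of 0.12 at percentile 99.6. In the metabolic lists, Pdk4, a kinase that restrains pyruvate oxidation, was at 1394 against 537, and Scd1, a fatty acid desaturase, at 399 against 179. The medians of lipid uptake and of fatty acid synthesis were -0.03 and 0.05, at percentiles 32.8 and 72.9. Inflammatory cytokines and chemokines had a median of -0.09 at percentile 2.87 and a mean of 0.03. Within that list Ptgs2, which encodes cyclooxygenase 2, was at 742 against 334, while Tnf was at 486 against 552. M-CSF macrophage markers had a median of -0.06 at percentile 12.9, with Csf1r, the M-CSF receptor, at 105159 in db/db and 120627 in db/+. E330013P06, a long noncoding RNA picked on these samples because the study is known to have followed it up, was at 69.7 against 26.6, a ratio of 2.62 (1.39 to 5.21), and at 2.2 and 2.3 in the GM-CSF libraries. RNA of whole cultures does not show which cells held this transcript, and most stromal markers were also at least 2-fold higher in db/db M-CSF.

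The genes with the highest log2 folds in this comparison had low counts. Grb14, an adaptor that inhibits the insulin receptor, was at 61.9 in db/db against 5.7 in db/+ (ratio 10.8, interval 3.42 to 55.1). Igj, the immunoglobulin joining chain of plasma cells, was at 161 against 24.7, and Cxcr7, a receptor for CXCL12, at 53.1 against 6.7. Car3, a carbonic anhydrase, was at 21.8 against 0, with an interval of the ratio from 2.67 upwards. Arhgap28, Ptprz1, Nrn1, Wnt10b, Bmp5 and Galnt13 completed the 10 highest, with log2 folds from 2.18 to 2.24. The 10 lowest included Pcdh12 at 0 against 22.8 (interval of the ratio 0 to 0.330), Xlr3a at 4.3 against 35.2, Muc19 at 6.1 against 41.8, Dnahc5 at 1.7 against 21.9, Ano7 at 2.6 against 20.9 and Scn4a at 7.0 against 33.3. Gm14151 was at 3.5 against 21.9, and the near-identical copies Sprr2a1 and Sprr2a2, whose reads are uncertain, had the same values of 5.2 and 33.3. Of the 106 genes at least 2-fold lower, 98 (92.5%) had under 100 normalised reads in both M-CSF libraries, and they were lower in the library with fewer olfactory receptor genes above 0.

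**Figure D1:**
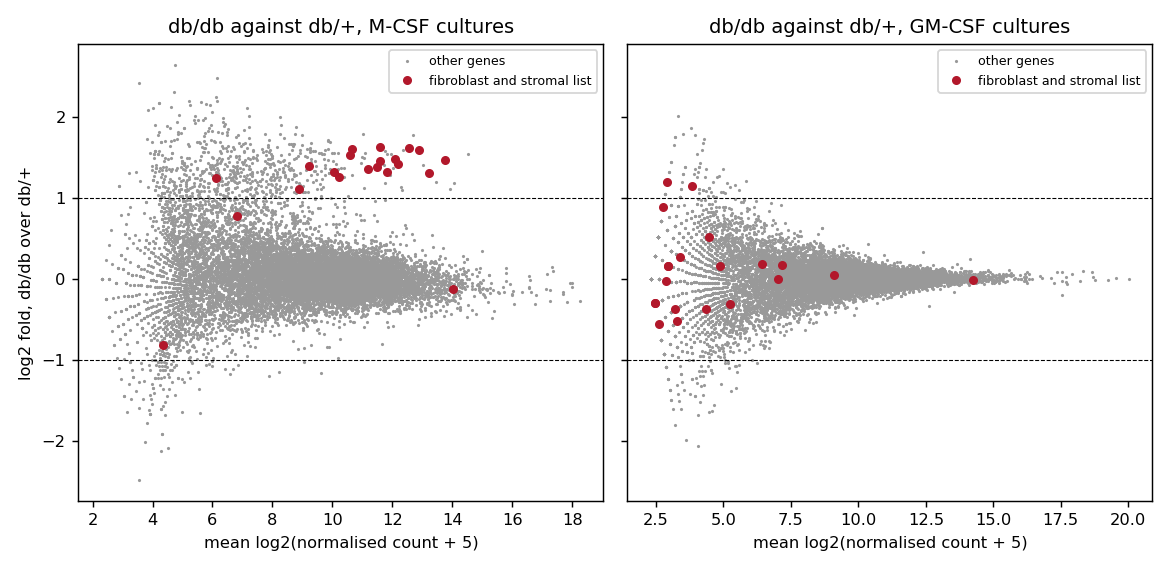
Log2 fold of db/db over db/+ (vertical axis) against the mean log2(normalised count + 5) of the 2 libraries (horizontal axis) for 13642 genes in M-CSF and in GM-CSF cultures, 1 point per gene, with fibroblast and stromal markers in red and dashed lines at 2-fold. In M-CSF the red points gather around a median of 1.38 and 689 genes lie above the upper line, against 80 in GM-CSF.

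The same question was asked of cells grown in GM-CSF, where the libraries labelled with the opposite genotypes differed little. Itgax, the integrin CD11c that marks these cultures, was at 56042 normalised reads in db/+ and 56259 in db/db. Mmp12, macrophage elastase, was at 401959 and 426470.0, and Spp1 at 192050.0 and 188741. In all, 80 genes were at least 2-fold higher and 65 at least 2-fold lower in db/db, a total of 145 against a mean of 163 and a range of 140 to 198 in draws from sampling of read pairs alone. With the level minimum at 200 the total was 13 against 22.2 from sampling.

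The genes with the highest log2 folds in GM-CSF had few reads. Mapk13, a p38 kinase, was at 21.5 in db/db against 2.3 in db/+, a ratio of 9.59 with an interval of 1.36 to 416. Map6d1 was at 15.1 against 0, with an interval of the ratio from 1.38 upwards, and the granule gene Olfm4 and the urea transporter gene Slc14a1 were both at 11.8 against 0, with an interval from 1.004 upwards. Dact3 was at 23.7 against 3.4, Fn3k, an enzyme that removes sugars from glycated proteins, at 26.9 against 5.6, and Inpp5j at 30.1 against 5.6. At the other end Rufy4 was at 3.2 against 29.2, Zfp13 at 7.5 against 33.7, Fam83d at 8.6 against 37.0, Ksr2 at 9.7 against 38.1, and Smad9 at 0 against 10.1, with an interval of the ratio from 0 to 1.22.

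In the lists, M-CSF macrophage markers were higher in db/db GM-CSF in 21 of 28 members (median log2 fold 0.05, percentile 99.5) and scavenger, complement and Fc receptor genes in 22 of 27 (median 0.05, percentile 99.9). These lists share Mertk, Stab1, Fcgr1 and the C1q genes, so they are not separate observations. Growth factors and wound repair genes were lower in 11 of 14 (median -0.09, percentile 0.92). The other 29 lists lay inside the middle 95% of random lists. Among 32 lists, some would lie outside it by chance. Fibroblast and stromal markers had a median of 0.05, or 0.17 with genes at 0 set to 3 read pairs, and only 8 of their 21 measured members reached the minimum in a GM-CSF library. Interferon-stimulated genes had 19 members above and 19 below 0, with a median of 0.01, and MHC class II genes also had a median of 0.01.

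**Figure D2:**
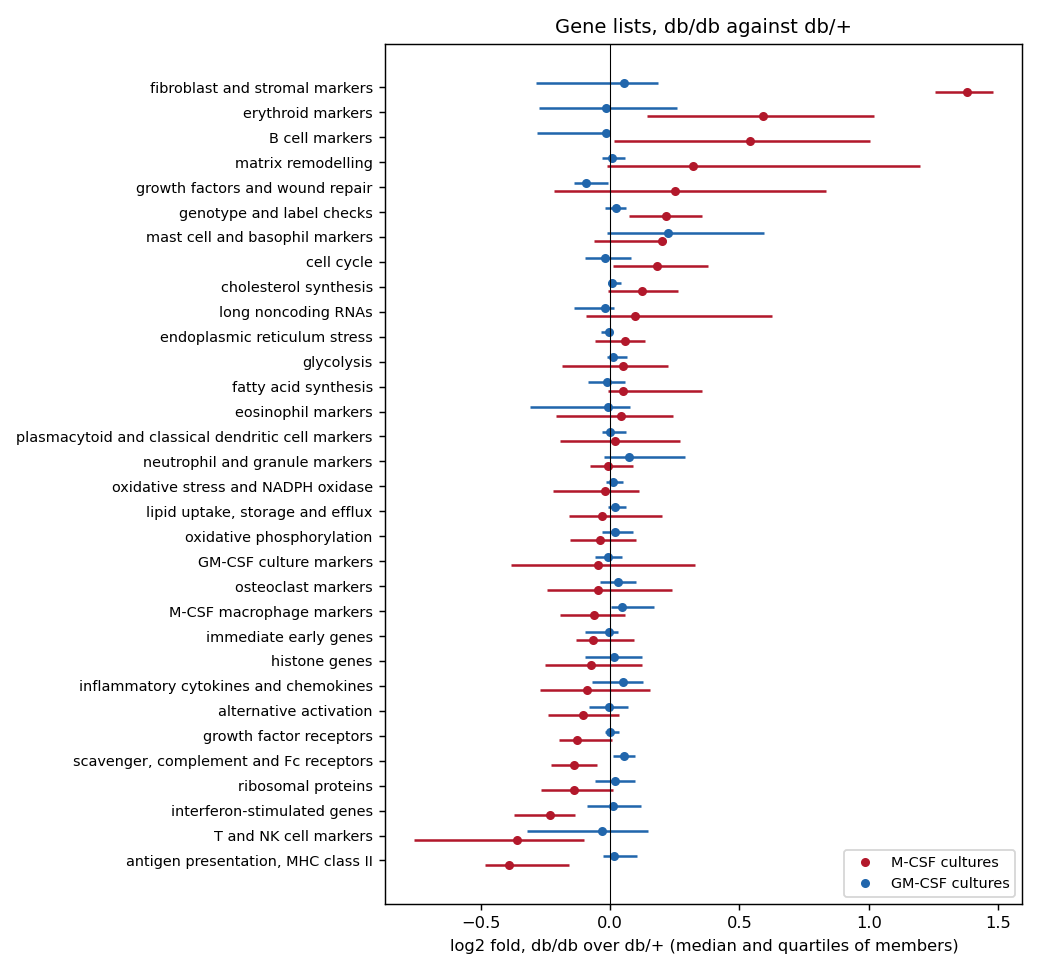
Median log2 fold of db/db over db/+ (horizontal axis) for the measured members of each of 32 gene lists (vertical axis), with M-CSF in red, GM-CSF in blue, and lines from the lower to the upper quartile of members. The stromal list stands at 1.38 in M-CSF and 0.05 in GM-CSF, and the interferon list at -0.23 and 0.01.

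The spread between the GM-CSF libraries was close to that of counting. For genes with 200 to 1000 reads the mean squared deviation between the genotypes was 1.01 times the sampling variance of read pairs in GM-CSF and 5.93 times in M-CSF; over single reads, were mates not counted separately, these would be 2.02 and 11.9. Above 50000 reads it was 27.6 times in GM-CSF, over 103 genes whose median absolute log2 fold was 0.03, with Rn45s, the ribosomal RNA precursor, the farthest at 0.19. The coefficient of variation beyond counting was 1.84% between the GM-CSF libraries and 15% between the M-CSF libraries.

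**Figure D3:**
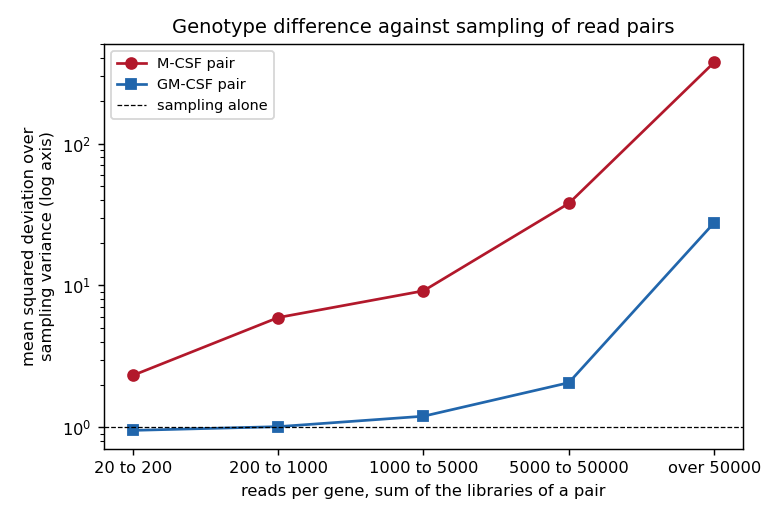
Mean squared deviation between the db/db and db/+ libraries divided by the sampling variance of read pairs (vertical log axis, no unit) by reads per gene (horizontal axis), for the M-CSF pair and the GM-CSF pair, with a dashed line at sampling alone. The GM-CSF pair lies at 0.950 to 2.06 up to 50000 reads and the M-CSF pair at 2.32 to 37.8.

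Across both cultures, few genes had a genotype fold past the threshold in the same direction, most of them on few GM-CSF reads. Cdh2, which encodes N-cadherin, was at 583 in db/db against 219 in db/+ M-CSF and at 22.6 against 5.6 in GM-CSF. Serpinh1, a collagen chaperone, was at 4609 against 1767 in M-CSF and at 6.5 against 0 in GM-CSF. Ehd3 was at 204 against 84.6 and at 10.8 against 0, and Gm15663, Slc2a13, Yes1, Col8a2, Pcdha10, Sparc and Dlg5 completed the 10 highest. Among those lower in both, the T and NK cell marker Cd2 was at 0 against 10.5 and at 7.5 against 22.4, the kinase gene Mapk10 at 0.9 against 11.4 and at 10.8 against 29.2, and Hrnr at 53.1 against 120 and at 0 against 6.7. On log2(normalised count + 5), 17 genes were at least 2-fold higher in db/db and 4 at least 2-fold lower in both cultures, a total of 21, while 12 went in opposite directions. A GM-CSF library stood at 0 for 10 of the 21 and 7 of the 12, and with libraries at 0 set to 3 read pairs the counts were 10 and 5. The interval of the GM-CSF ratio excluded 1 for 1 of the 21, Zfp13, which was lower, and for 0 of the 12. With a pseudocount of 1 these counts were 121 in the same and 127 in opposite directions, and with no filter 24 and 28. Independent lists of the same sizes would share 4.55 in the same direction and 3.90 in opposite directions. Those figures take every kept gene as equally likely to be called. Calls gathered in genes with few reads, with the GM-CSF total falling from 145 to 13 at a level minimum of 200. The figures are therefore no chance level for these counts. Grb14, Ephb3, Smad9, Shisa4 and Msrb3 had the largest differences between the genotype folds with M-CSF above GM-CSF, and Srcin1, Inpp5j, Pou3f1, Sprr2a1 and Sprr2a2 with M-CSF below; those differences were not tested. Across all 13642 genes the folds of the M-CSF and GM-CSF comparisons, which share no library, had a Pearson r of 0.00941 and a Spearman rho of -0.0113; genes are not independent replicates.

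In the additive limma model of genotype and culture, which has 1 residual degree of freedom, Sparc alone of 13642 genes passed for genotype, higher in db/db in both cultures, with a log2 fold of 1.37, an SE of 0.16 and an adjusted p of 0.0114. In GM-CSF that gene had a ratio of 3.60 with an interval of 0.702 to 35.1, from 4.5 normalised reads in db/+ and 16.1 in db/db. A gene's error in this model comes from the difference between its genotype folds in M-CSF and GM-CSF. The test therefore takes the GM-CSF libraries as separate cultures of the opposite genotypes, which the closing section leaves open. The next were Timp3 at 1.27 with an adjusted p of 0.0542, Serpinh1 at 1.29 with 0.145, Col1a2 at 0.99 with 0.240, and Aldh1l2, a mitochondrial folate enzyme, at 1.25 with 0.255. At an unadjusted p under 0.05 limma gave 603 genes. That is a share under 0.05 of the 13642 tested, so no more than expected with no genotype effect. The edgeR test on the recovered reads gave 103 genes at an adjusted p under 0.05, 101 of them higher in db/db. The edgeR test took single reads, not read pairs, and a gene could pass it on its M-CSF reads alone. Sparc passed, but so did Ctgf (edgeR adjusted p = 3.16e-04), at 5.6 in db/+ and 4.3 in db/db GM-CSF. How many of the 103 were higher in both cultures was not counted. With a pseudocount of 20 (smallest adjusted p = 0.330), without a variance trend or without the culture factor, limma gave 0.

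Of the 32 lists, 5 passed camera for genotype at the preset correlation of 0.01. Fibroblast and stromal markers were higher (median log2 fold 0.74, camera adjusted p = 2.68e-17), with 1 of 21 members passing over all genes and 12 adjusted over the list alone. Matrix remodelling genes were higher (camera adjusted p = 2.29e-06), with 0 of 26 passing over all genes and 7 adjusted over the list alone. Interferon-stimulated genes were lower (median -0.12, camera adjusted p = 3.55e-07), as were MHC class II genes and ribosomal proteins (camera adjusted p = 0.0416 each), with 0 members passing either way. Each of these 5 lists had an adjusted p = 0.943 with an estimated correlation. A main-effect fold averages the M-CSF and GM-CSF folds, and all 5 lists stood apart from random lists in M-CSF alone. Their medians in M-CSF and GM-CSF were 1.38 and 0.05 for stromal markers and 0.32 and 0.01 for matrix remodelling. They were -0.23 and 0.01 for interferon-stimulated genes, -0.39 and 0.01 for MHC class II, and -0.14 and 0.02 for ribosomal proteins. The growth factor receptors had 0 members passing over all genes and 1 adjusted over the list alone, and in the other 26 lists 0 members passed either way. For growth factor receptors the median was -0.10, the mean 0.02 and the camera direction down. M-CSF macrophage markers, inflammatory genes and dendritic cell markers had medians of 0.01, 0.01 and 0.04 with camera directions down, alternative activation had a median of 0.01 and a mean of -0.02, and osteoclast markers had a median of -0.04 with a mean of 0.05.

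The second question was how cells grown in GM-CSF differed from cells grown in M-CSF. The cultures differed widely in both genotypes: GM-CSF cultures had more transcripts of CD11c, eosinophil-type ribonucleases, arginase and glycolytic and cholesterol synthesis enzymes, and fewer transcripts of resident macrophage markers, interferon-stimulated genes and collagens. Itgax was at 775 normalised reads in db/+ M-CSF and 56042 in db/+ GM-CSF, and limma gave it a log2 fold of 6.05 with an SE of 0.09 and an adjusted p of 2.33e-15. Slc7a2, a transporter of arginine, rose by 7.94 (SE 0.09, adjusted p = 1.75e-16) and Mgll, the monoacylglycerol lipase, by 6.79 (SE 0.09, adjusted p = 2.20e-15). Clec4a1, a C-type lectin of monocytes, fell by 7.40 (SE 0.11, adjusted p = 2.33e-15) and Tmem176b fell by 5.83 (SE 0.09, adjusted p = 3.06e-15). In all, limma called 7787 of 13642 genes for culture type, 4062 higher and 3725 lower in GM-CSF. This test takes the GM-CSF libraries as separate cultures, which the closing section leaves open. With median-of-ratios scaling the split was 3882 higher and 3907 lower, with folds centred on their median 3610 higher and 4061 lower, with no filter 3900 and 4224, without a variance trend 2859 and 2946, and with edgeR on the recovered reads 3763 and 3983. With a level minimum of 200 it leaned the other way, with 3690 higher and 2659 lower.

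By size alone, 1632 genes were at least 2-fold higher and 2139 at least 2-fold lower in GM-CSF in db/+ cells, and 1546 and 2156 in db/db cells. Sampling of read pairs alone gave means of 132 and 91.9. The comparisons share no library, although the GM-CSF libraries may share a pool of cells or RNA. In both comparisons 1351 genes were higher and 1800 lower, and 1 went in opposite directions. Independent lists would share 523 in the same and 500 in opposite directions. Across genes, which are not independent replicates, the folds had a Pearson r of 0.947 and a Spearman rho of 0.898. The balance of genes at least 2-fold higher and lower in GM-CSF depended on the filter. At a level minimum of 200, 1225 were higher and 1093 lower in db/+ cells, and 1166 and 1059 in db/db cells. With no filter, 1710 were higher and 3322 lower in db/+ cells, and 1665 and 2805 in db/db cells. The M-CSF libraries had the broader low-level signal, with reads on 526 olfactory receptor genes in db/+ and 331 in db/db. In GM-CSF these were 114 and 96. How far that signal adds to the genes lower in GM-CSF was not tested.

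The highest folds in both genotypes belonged to Ccl17, a chemokine for T cells, at 3163 in db/+ GM-CSF from 2.8 in M-CSF (ratio 1108, interval 259 to 15422), and to Nov, a matricellular growth regulator, at 20233 from 68.5. Arg1, which encodes arginase 1, was at 14049 from 52.3, the betaine transporter gene Slc6a12 at 5794 from 21.9, the chemokine gene Ccl6 at 312883 from 1985, and F7, coagulation factor VII, at 5740.2 from 34.2. Ear6 and Ear7, eosinophil-associated ribonucleases, and Klk1b1, a kallikrein, were at 2416, 1778 and 1514 in db/+ GM-CSF, but each has close copies whose reads are uncertain. The lowest folds in both genotypes belonged to Ctgf, a connective tissue growth factor, at 5.6 from 5093, and to Sparc, Col1a2, Serpinh1, Bgn, Tnc, Col5a2 and Col6a1, all of them matrix or collagen genes. Serpinh1 was at 0 in db/+ GM-CSF from 1767, at least 263-fold lower with 3 read pairs as the floor in each library. Mpo, the neutrophil peroxidase, was at 1.1 from 1448, and Id3, an inhibitor of helix-loop-helix factors, at 2.3 from 1565.

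M-CSF macrophage markers fell in 22 of 28 members in GM-CSF, and 1 rose and 5 did not pass (23 fell and 1 rose adjusted over the list alone; camera adjusted p = 1.93e-13, adjusted p = 0.706 with an estimated correlation). Stab1, a scavenger receptor, was at 1216 from 75415 in db/+, Cx3cr1, the fractalkine receptor, at 52.7 from 6301, Apoe at 27165 from 267107, and Csf1r at 33549.6 from 120627. Ccl2, a monocyte chemokine, was the member that rose, to 1626 from 240. GM-CSF culture markers rose in 22 of 30 members and fell in 6 (camera adjusted p = 1.24e-04, adjusted p = 0.706 with an estimated correlation). Besides Itgax and Ccl17, these included Clec7a, the beta-glucan receptor, at 28171 from 3058 and Fabp4 at 8828 from 422, while Cd83 and Ciita fell. The MHC class II list rose in 8 and fell in 5 of 15 members (median log2 fold 0.32, mean -0.18, camera direction down, adjusted p = 0.974). Cd74 was at 76588 from 49679.8 in db/+, and H2-Aa, H2-Ab1, H2-Eb1, H2-DMb1 and H2-Oa rose as well. The class II genes Ciita and H2-DMa fell (log2 folds -1.09 and -0.82). So did Cd83 (-2.23) and Cd86 (-0.96), which are not class II genes, as is Cd40, at 12.3 from 404.

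Interferon-stimulated genes fell in 36 of 38 members in GM-CSF and 0 rose (37 fell adjusted over the list alone), with a median log2 fold of -2.39 (camera adjusted p = 1.19e-19, adjusted p = 0.706 with an estimated correlation). Ifit3 was at 63.9 from 3611 in db/+, Irf7, the master regulator of the interferon response, at 166 from 5663, and Isg15 at 79.6 from 702. Fibroblast and stromal markers fell in 20 of 21 members, with a median of -6.82 (camera adjusted p = 1.93e-13, adjusted p = 0.706 with an estimated correlation). Fstl1 was the exception and rose, at 19499.7 from 1867 in db/+. Neutrophil and granule markers fell in 13 of 19 members and rose in 3 (camera adjusted p = 8.93e-04, adjusted p = 0.706 with an estimated correlation), with Ngp at 35.9 from 3536 and S100a9 at 140 from 5749.7, while Chi3l3, Mmp8 and Ly6c2 rose. The list's median in db/+ was -4.34, or -3.15 with genes at 0 set to 3 read pairs. Histone genes fell in 45 of 48 members (median -0.95, camera adjusted p = 1.99e-11, adjusted p = 0.706 with an estimated correlation), although reads shared between near-identical histone copies are uncertain.

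Glycolysis genes rose in 24 of 26 members in GM-CSF, with a median log2 fold of 1.88 (camera adjusted p = 1.93e-13, adjusted p = 0.706 with an estimated correlation). The glucose transporter gene Slc2a1 was at 6552 from 669 in db/+, Aldoc, an aldolase, at 4109.5 from 104, and Egln3, an oxygen sensor, at 2291 from 59.9, while Pfkm fell. Cholesterol synthesis genes rose in all 24 members (camera adjusted p = 1.60e-11, adjusted p = 0.706 with an estimated correlation), with Mvd at 3043 from 418. Endoplasmic reticulum stress genes rose in 20 of 24 members and 1 fell (20 and 2 adjusted over the list alone; camera adjusted p = 1.55e-07, adjusted p = 0.706 with an estimated correlation), among them Hspa5, the chaperone BiP, at 60864 from 23954. Oxidative phosphorylation genes rose in 32 of 38 members and 1 fell (34 and 1 adjusted over the list alone; median 0.52, camera adjusted p = 2.46e-06, adjusted p = 0.706 with an estimated correlation). Fatty acid synthesis genes rose in 13 of 19 and fell in 3 (camera adjusted p = 8.32e-04, adjusted p = 0.726 with an estimated correlation), with the desaturase gene Scd2 at 22261 from 827. Lipid uptake and storage genes rose in 17 of 29 and fell in 8 (camera adjusted p = 0.0377, adjusted p = 0.0866 at a level minimum of 200 and 0.774 with an estimated correlation), with the oxidised lipoprotein receptor gene Olr1 at 839 from 21.9.

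Alternative activation genes rose in 14 of 22 members in GM-CSF and fell in 7 (camera adjusted p = 0.0119, adjusted p = 0.726 with an estimated correlation). Besides Arg1 and Ccl17, the chitinase-like gene Chi3l3 was at 32859 from 1027 in db/+ and the checkpoint ligand gene Pdcd1lg2 at 1096 from 15.2, while Il10 was at 0 from 238, at least 35.3-fold lower. Osteoclast markers rose in 9 of 12 members and fell in 3 (camera adjusted p = 0.00286, adjusted p = 0.706 with an estimated correlation), with the collagenase Ctsk at 10565 from 180 and the acid phosphatase Acp5 at 7305 from 404. Eosinophil markers rose in 6 of 8 and fell in 2 (camera adjusted p = 0.0411, adjusted p = 0.706 with an estimated correlation), and the members that fell were the eotaxin receptor gene Ccr3, at 2.3 from 145, and Prg2. For every list of the culture comparison given with counts over all genes alone, the counts adjusted over the list alone were equal to them.

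Inflammatory cytokines and chemokines went both ways, with 12 of 27 members higher and 9 lower (12 and 11 adjusted over the list alone; camera adjusted p = 0.310). Il1a was at 1643 from 15.2 in db/+ and Ccl4 at 1229 from 177, while Ptgs2 was at 37.0 from 334. Scavenger, complement and Fc receptor genes rose in 10 and fell in 12 of 27 members (median log2 fold -0.01, mean -0.79, camera adjusted p = 0.175), with complement C3 at 22462 from 4034 and C1qa at 2980.0 from 22537. Matrix remodelling genes rose in 13 and fell in 10 of 26 (camera adjusted p = 0.420), with Mmp12 at 401959 from 4085. Growth factor receptors rose in 5 and fell in 3 of 9 (camera adjusted p = 0.420), with Kit at 2614 from 106 and Csf2rb, the signalling chain of the GM-CSF receptor, at 42046 from 6448.

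**Figure D4:**
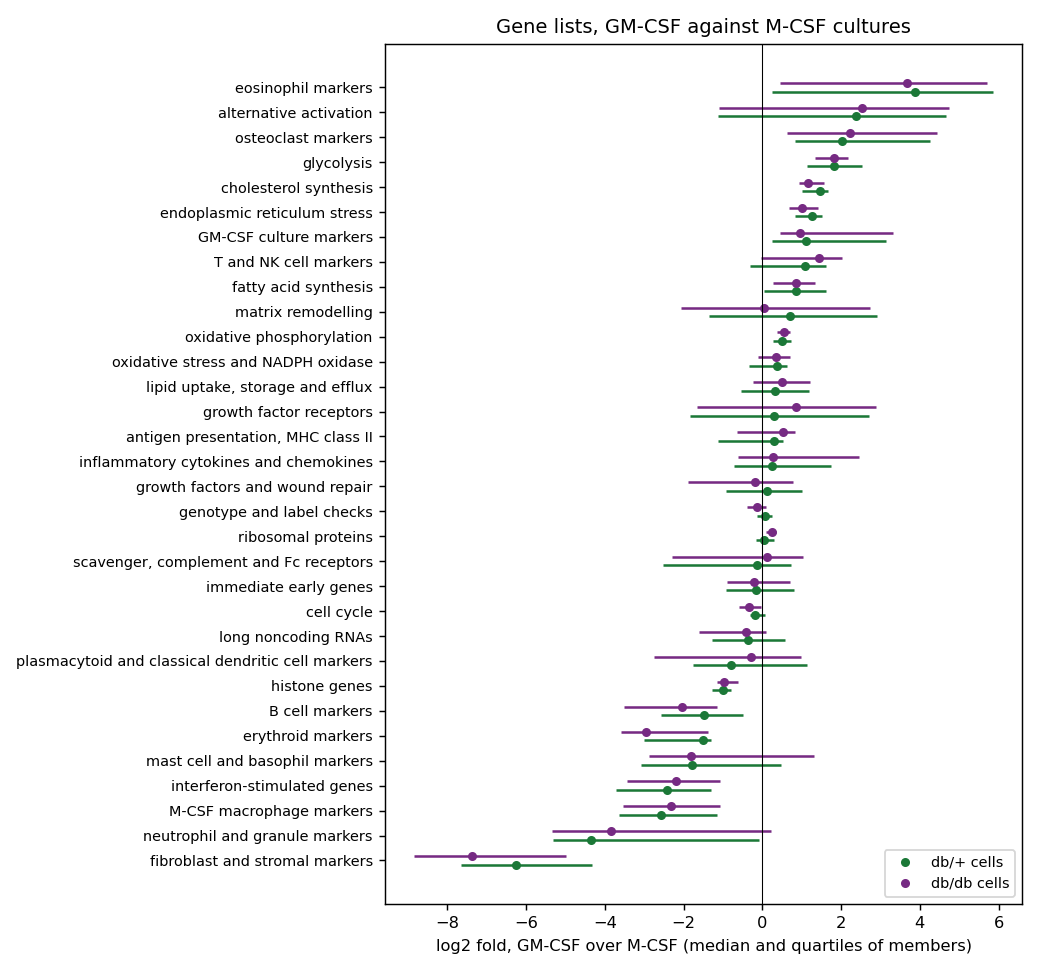
Median log2 fold of GM-CSF over M-CSF cultures (horizontal axis) for the measured members of each of 32 gene lists (vertical axis), with db/+ cells in green, db/db cells in purple, and lines from the lower to the upper quartile of members. Glycolysis lies at 1.82 and 1.81 and interferon-stimulated genes at -2.43 and -2.19 in db/+ and db/db, and stromal markers at -6.26 and -7.38 (-7.20 in db/db with genes at 0 set to 3 read pairs).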

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

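The tests of explanations in this part were all chosen only after the results they bear on were seen, while the rule that picked the next 12 genes was set earlier. On log2(normalised count + 5), these genes were at least 2-fold higher in db/db than in db/+ cells in one culture type and at least 2-fold lower in the other, and the difference between the cultures was not tested. In 10 of them db/db was higher in M-CSF and lower in GM-CSF: the log2 fold in M-CSF minus that in GM-CSF was 2.96 for Smad9, 2.82 for Msrb3, 2.52 for Syde1, 2.49 for Six4, 2.34 for both Scx and Zfpm2, 2.29 for Rem1, 2.27 for Steap1, 2.17 for Nr2f2 and 2.10 for Zfp365. In the other 2 the order was opposite, with a difference of -2.89 for Srcin1 and -2.27 for Fgfr3. The largest GM-CSF value among the 12 genes was 46 normalised reads, in Rem1, a GM-CSF library stood at 0 for 7 of them, 5 were left with libraries at 0 set to 3 read pairs, and the interval of the GM-CSF ratio excluded 1 for 0 of them. Independent lists of the same sizes would share 3.90 genes in opposite directions, but that takes all kept genes as equally likely to be called. Calls gathered in genes with few reads, so 3.90 is no chance level here.

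Stromal genes were higher in db/db M-CSF, with a median log2 fold of 1.38 for the fixed list. A scaling factor common to all genes is argued against, since the list stood above the median fold of all kept genes, which was 0.02. With that median set to 0, the list's median was 1.36. The deposited values were already scaled, so centring could move it little and was no separate test. A larger share of stromal cells in that culture and transcription of these genes by db/db macrophages themselves cannot be told apart, because RNA came from whole cultures with no sort named in the labels and the GM-CSF median of 0.0526 rests on a list with only 8 of 21 members past the minimum there. A second list of 42 stromal genes, written after the result and sharing no gene with the other fixed lists, had a median of 1.36 (quartiles 1.15 and 1.53), which both explanations allow. Both lists together took 0.795% (0.790% to 0.80%) of db/db reads against 0.337% (0.334% to 0.340%) in db/+. The genotype of the donors stays open as an untested cause.

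The GM-CSF libraries of the opposite genotypes differed by about the sampling of read pairs. A single library under both names is argued against, since genes above 50000 reads deviated by 26.0 times the sampling variance after their median fold was set to 0. Libraries made from 1 pool of cells or RNA and separate cultures that hardly differ in GM-CSF cannot be told apart, because no pair of cultures of the same genotype gives a yardstick: the ratio of 1.12 over genes of 200 to 5000 reads (2.24 over single reads) and the coefficient of variation of 1.84% describe the pattern itself. Until that is settled, the GM-CSF comparison may say little about the genotype. With 1 pool, the SEs and p-values of the culture type test would also not cover variation between GM-CSF cultures. The GM-CSF pair would then hold no genotype contrast. The genotype main effect, its SEs and its limma and camera p-values would not describe the genotype across both cultures.

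Interferon-stimulated and MHC class II genes were lower in db/db M-CSF. In these libraries, dilution of macrophage RNA by stromal RNA is argued against as the whole cause by the medians. The interferon median lay 0.17 below that of the M-CSF macrophage markers (difference -0.17, bootstrap interval -0.28 to -0.04). The MHC class II median lay further down (difference -0.33, interval -0.45 to -0.02). The intervals resample genes, which are not independent replicates, so they may be too narrow, and the MHC class II bound is near 0. They cover no variation between cultures. A scaling factor common to all genes is argued against as well, but only in that both lists lay below the median of kept genes. With that median set to 0, the interferon median was -0.26 and its upper quartile -0.16. The MHC class II median was -0.41 and its upper quartile -0.18. Since the median fold of kept genes was 0.02, centring could only lower these values and was no separate test. The db/db genotype cannot be told apart from a difference between single cultures, because there was 1 library per group. Camera with an estimated correlation (adjusted p = 0.943 for interferon-stimulated genes) passed 0 lists for genotype and for culture type alike, so it decides nothing here.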

How the results depend on the processing

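Of the alternatives, only the level minimum reached in 1 of the 2 libraries compared and libraries at 0 set to 3 read pairs were chosen after seeing the data. In the M-CSF genotype comparison the total of 795 genes was 471 with a pseudocount of 20, 1366 with no filter (812 higher and 554 lower, against 689 and 106), 334 with a level minimum of 200, 1661 at 1.5-fold and 149 at 3-fold, and the other alternatives gave 766 to 972. In GM-CSF the total of 145 was 560 with a pseudocount of 1, 1 with 20, 316 with no filter, 13 at a minimum of 200, 691 at 1.5-fold, 18 at 3-fold, 73 with the minimum reached in 1 of the 2 libraries compared, and 106 with libraries at 0 set to 3 read pairs. Between the cultures, the db/+ total of 3771 was 2318 at a minimum of 200, 5945 at 1.5-fold and 2241 at 3-fold, and the db/db total of 3702 was 2225, 5826 and 2378. At the minimum of 200 the split turned, from 1632 higher and 2139 lower to 1225 and 1093 in db/+, and from 1546 and 2156 to 1166 and 1059 in db/db. The 21 genes apart in the same direction in both cultures became 121 with a pseudocount of 1, 0 with 20, 24 with no filter and 6 at a minimum of 200, while the 12 in opposite directions became 127, 0, 28 and 2, so the excess of the same direction was absent with a pseudocount of 1 and with no filter. With libraries at 0 set to 3 read pairs these counts were 10 and 5. Thresholds and filters move such counts by construction; for the pseudocounts the cause was not tested. For the genotype effect, limma called 1 gene, and 2 with a pseudocount of 1, 3 at a minimum of 200 and 2 with median-of-ratios scaling. It called 0 with a pseudocount of 20 (629 at an unadjusted p under 0.05), 0 without a variance trend (617) and 0 without the culture factor (1). Each of these unadjusted counts was a share under 0.05 of the 13642 genes tested, so no more than expected with no effect. The edgeR test on the recovered reads called 103, and the cause was not tested. For the culture effect the alternatives called between 5805 and 8124 genes, the largest number with no filter, where 21265 genes were tested; whether the same genes were called was not compared. With an estimated correlation, the 5 lists passing camera for genotype and the 15 for culture type both became 0; with 1 residual degree of freedom that correlation is poorly determined, and the cause was not tested. At a minimum of 200 the lipid uptake list did not pass for culture type (adjusted p = 0.0866), which left 14 lists. Of the named genes' folds under other pseudocounts and scalings, 11316 stayed within their counting interval, 60 moved beyond it and 0 reversed; of the list medians, 239 stayed and 5 moved. No pairing by replicate number was possible because each group has 1 library; the additive model compares the genotypes within each culture type, and the fit without the culture factor is given above. Leaving out a culture or a genotype leaves 1 library per group, a fold with no test, which the pairwise comparisons give. DESeq2 was not run, since the plan set edgeR as the test for reads recovered from normalised values. Depth limits the low genes most: a gene at 0 may stand at up to 3 read pairs, 5.23 to 6.73 normalised reads.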

Other observations

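No test in this part was chosen after its result was seen. Markers of other marrow cells were also read in these cultures, most of them at low levels. Plasmacytoid and classical dendritic cell markers rose in 7 and fell in 8 of 17 members from M-CSF to GM-CSF (camera adjusted p = 0.307). Siglech, a receptor of plasmacytoid dendritic cells, was at 6.7 in GM-CSF from 342 in M-CSF db/+ cells and Tcf4, a transcription factor of that lineage, at 412 from 2892, while Clec9a, a receptor of cross-presenting dendritic cells, was at 640.4 from 24.7 and Cd24a at 5656 from 294. Mast cell and basophil markers rose in 2 and fell in 5 of 8 (camera adjusted p = 0.485), with the basophil protease Mcpt8 at 1.1 from 73.2. B cell markers fell in 6 of 9 and 1 rose (camera adjusted p = 0.105), with Cd79b at 20.2 from 203 and Cd22 at 3573 from 327. Erythroid markers fell in 4 of 6 and 1 rose (5 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.149), but the globin copies share reads and are uncertain. T and NK cell markers rose in 2 and fell in 1 of 4 (camera adjusted p = 0.910), with Cd4 at 61.7 from 851.

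Immediate early genes rose in 7 and fell in 9 of 19 members in GM-CSF (median log2 fold -0.28, mean 0.02, camera adjusted p = 0.833). Fos, a partner in the AP-1 factor, was at 643 from 2918 in db/+ cells and Egr1 at 122 from 343, while Jun was at 7491 from 3316 and Egr2 at 3829 from 326. Oxidative stress and NADPH oxidase genes rose in 14 and fell in 5 of 25 (15 and 6 adjusted over the list alone; camera adjusted p = 0.133), with the cystine transporter gene Slc7a11 at 12047 from 305 and Txnip at 2848 from 17861. Cell cycle genes rose in 3 and fell in 11 of 33 (2 and 8 adjusted over the list alone; camera adjusted p = 0.133), with Ccnd1 at 308 from 1479. Long noncoding RNAs rose in 3 and fell in 8 of 15 (4 and 8 adjusted over the list alone; camera adjusted p = 0.310): E330013P06 was at 2.3 from 26.6, Dnm3os at 4.5 from 207, and Malat1 at 87537 from 162563. Ribosomal protein genes rose in 16 of 52 and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 0.170). Growth factors and wound repair genes rose in 6 and fell in 5 of 14 (camera adjusted p = 0.857), with the platelet-derived growth factor gene Pdgfb at 201 from 3154. The label-check list rose in 1 and fell in 2 of 6 (median -0.05, mean 0.18, camera adjusted p = 0.833). In M-CSF, the genotype median was 0.59 over 6 erythroid markers (percentile 85.15, 2 at least 2-fold higher in db/db), 0.54 over 9 B cell markers (percentile 94.2, 3 at least 2-fold higher) and -0.36 over 4 T and NK cell markers (0.05 with genes at 0 set to 3 read pairs; percentile 6.5, 1 at least 2-fold lower), all inside the middle 95% of random lists. The genotype medians of neutrophil, eosinophil, mast cell, osteoclast and dendritic cell markers were -0.01, 0.04, 0.20, -0.05 and 0.02, at percentiles 24.0, 38.7, 59.3, 22.8 and 40.5.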
